A study of Mus musculus with 20 samples.

How the data were processed

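The submitters sequenced total RNA libraries for messenger and long non-coding RNA from frozen cerebral cortex on an Illumina HiSeq 4000. The mice were PS19 transgenic or wild type on a (C57BL/6 x C3H)F1 background, aged 3 or 10 months. There are 20 libraries, 5 in each of the groups WT03M, WT10M, TG03M and TG10M. Replicates carry numbers, and the labels do not say that each is a separate animal, so each p measures the spread between these samples. Per the labels, the values are FPKM per transcript, fragments scaled to transcript length and to the mapped fragments of the library. The submitters' processing notes name the build GRCm38 (mm10) and the tools CASAVA, TopHat2, Cuffdiff and DESeq2. The role, order and versions of these tools are not given in the sources used here. The deposited FPKM tables list 50660 mRNA transcripts of 21949 genes and 3611 other transcripts, made up of 2426 annotated non-coding transcripts, 561 lncRNAs assembled by the submitters and 624 transcripts of uncertain coding potential (TUCP).

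Gene values are sums of the FPKM of a gene's transcripts. A spreadsheet had turned 27 gene symbols into dates, and all 27 were restored by gene ID. Coordinates and current names are from GENCODE M21 on GRCm38. The tables hold no read counts. In 1892 genes with 1 transcript of over 4000 bases, low FPKM values lie near whole multiples of a step, from which the depth was estimated at 22.5 to 30.1 M fragments (M, mega) per library. The group medians were 23.3 in WT03M, 25.3 in WT10M, 26.2 in TG03M and 24.7 in TG10M. Of the low values, 70.7 to 88.6% lay within 0.1 of a whole multiple, against 20% for evenly spread values. The step was set from the most frequent of these values. Those near 1 step therefore lie there by construction, and 20% is not the exact share by chance. The sum of mRNA FPKM was 434898 to 479771 per library, and 12659 to 12804 genes had an FPKM of 1 or more. Between replicates of a group, log2 values of genes correlated with Pearson's r of 0.978 to 0.994, and at most 0.00729% of values were identical, so no library is a copy of another of its group.

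Genes with a mean FPKM of at least 0.5 over the 20 libraries (13722) were tested on log2(FPKM + 0.5) with limma (lmFit, contrasts and eBayes with a trend), two-sided. One fit with 1 mean per group and 16 residual degrees of freedom gave the comparisons of genotype at each age, of age in each genotype, and their interaction. Non-coding and TUCP transcripts with a mean FPKM of at least 0.1 (3413) were tested in the same way on log2(FPKM + 0.1) for genotype at each age and for age in wild type. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. No scaling was added to the authors' FPKM. Lists of marker and pathway genes were fixed before the data were examined. Of 36 lists, the 34 with at least 5 tested genes and not reported per gene were tested with camera of limma at a preset correlation between genes of 0.01, and again with the correlation estimated. The count adjusted over the list alone applies Benjamini-Hochberg to the members of that list.

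The genes named in the text follow a rule set before the data were examined. Among called genes with a mean FPKM of at least 1, and without predicted gene models, it takes the 10 largest rises and the 10 largest falls of each comparison. It adds Prnp and Mapt, up to 4 members with the smallest p of each list described, and, for non-coding transcripts, the 3 largest rises and the 3 largest falls. The genes plotted, the genes that mark sets of libraries and the RNAs listed at 0 in every WT library were chosen after the data were seen. The principal components were computed on the centred log2 values of the tested genes. The groups of libraries that differ on PC1 and in Hsp90aa1 were found from the values; the labels give no batch, date or sex.

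The fits were tested on simulated data, drawn with the real mean and spread of each gene, no group difference and known changes added. Of 100 genes changed by 1 on the log2 scale, 95 to 100 were called over the 5 comparisons, and of 100 changed by 0.5, 59 to 81, with 4.57 to 8.82% of calls false. For non-coding transcripts at 10 months 80 and 26 of 100 were called. A list shifted by 0.3 was called, with 0 other lists. These rates of false calls hold for the simulated data only. In other splits of the real libraries, the median count of lists with the preset correlation was 9 at 10 months and 7 at 3 months. For genes the median was 0 at both ages, but the highest counts were 3403 and 625. The simulation therefore gives no rate of false calls for the real libraries.

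Alternatives fixed before the data were examined were other pseudocounts (0.1 and 1 for genes, 0.01 and 1 for transcripts), other filters on low values, median centring and quantile normalization. Others were a fit of the compared groups alone, the replicate number as a block, array weights, a robust variance prior, transcripts in place of genes, the set test fry, and leaving out each library in turn. A covariate for sex was to be used if both sexes were present. Alternatives that leave out or adjust for the libraries that stand apart, or adjust for those low in Hsp90aa1, were chosen after seeing the data. Clec7a and Xist were not analysed here. The values of 1 named gene are not reported here. The versions were R 4.3.3, limma 3.58.1, Python 3.11.15, matplotlib 3.10.9 and BLAST 2.17.0.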

Results

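RNA was sequenced from the cerebral cortex of PS19 mice, which carry a mutant human tau transgene under the Prnp promoter (TG), and of wild-type mice (WT). The mice were 3 or 10 months old, giving the groups WT03M, WT10M, TG03M and TG10M with 5 libraries each. The steps between the smallest FPKM values put the depth at 22.5 to 30.1 M fragments per library. The comparisons ask which messenger and long non-coding RNAs differ with the transgene at each age, and which change with age in each genotype. Fold changes are differences of log2(FPKM + 0.5), which understate the change of genes with low values. Adjusted p is from limma with Benjamini-Hochberg adjustment over 13722 genes, and values after ± are SDs over the 5 libraries of a group.

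Prnp (ENSMUSG00000079037; GRCm38 chromosome 2, 131909928 to 131938429, plus strand), the prion protein gene whose promoter drives the transgene, was higher in transgenic cortex at both ages. It rose by 0.76 at 3 months (SE 0.06, adjusted p = 1.25e-06), from 436 ± 12.6 to 741 ± 44.3 FPKM. It rose by 0.83 at 10 months (SE 0.06, adjusted p = 2.83e-07), from 442 ± 48.4 to 785 ± 39.6 FPKM. The Prnp difference at 10 months minus that at 3 months was 0.07 (SE 0.09, adjusted p = 0.980). The transgene also carries untranslated Prnp sequence, so the Prnp values may count its RNA. Whether RNA of the endogenous Prnp gene rose cannot be told from these values. Mapt (ENSMUSG00000018411; chromosome 11, 104231390 to 104332090, plus strand), the mouse tau gene, had mean FPKM of 153 ± 6.61 in WT03M, 138 ± 15.4 in TG03M, 151 ± 13.8 in WT10M and 135 ± 9.69 in TG10M. The Mapt differences between genotypes, -0.15 at 3 months (adjusted p = 0.487) and -0.15 at 10 months (adjusted p = 0.367), did not pass.

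**Figure D1:**
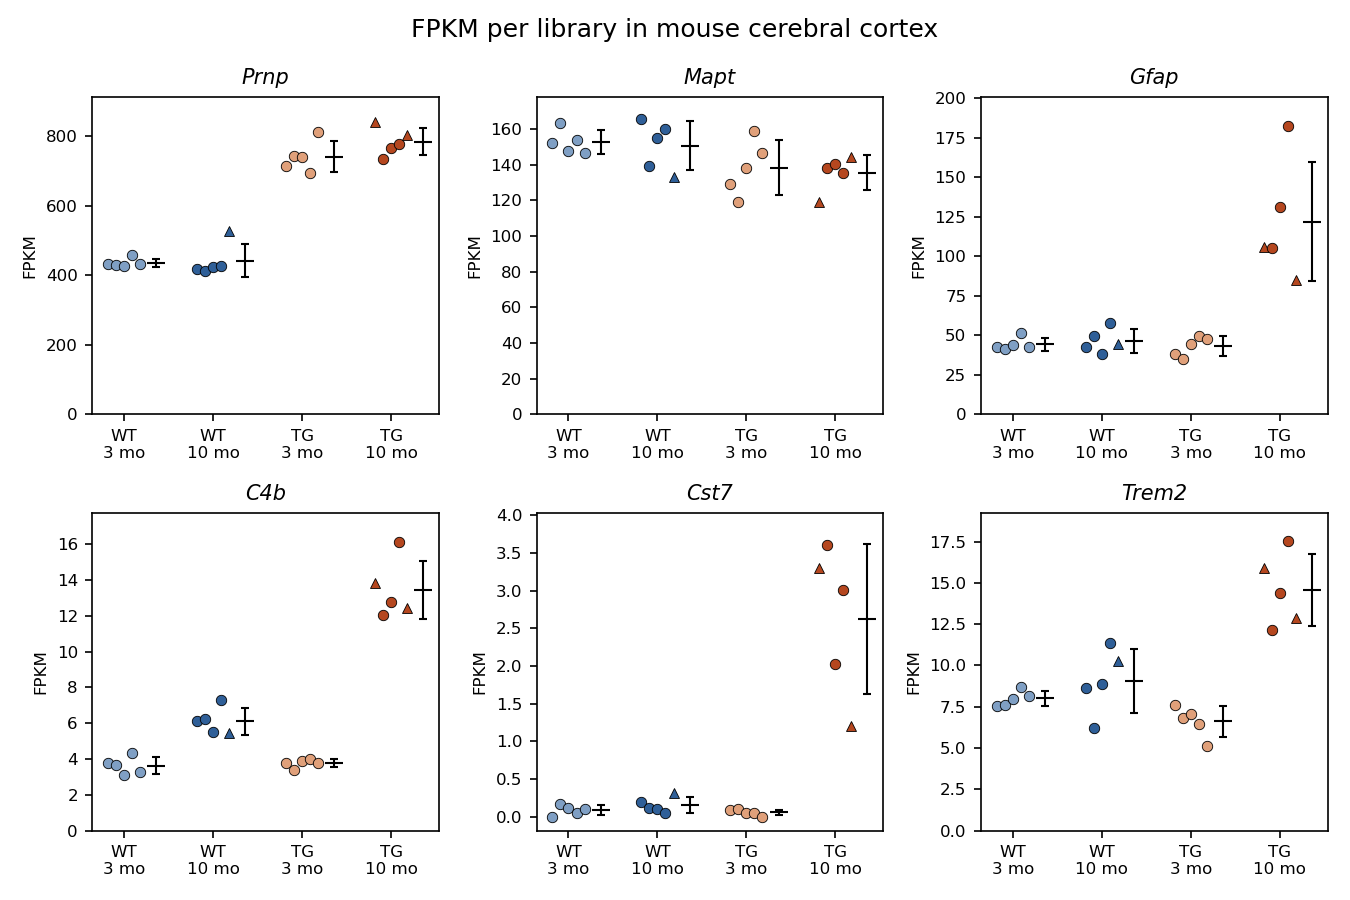
FPKM (vertical axes, linear) of Prnp, Mapt, Gfap, C4b, Cst7 and Trem2 in each library, by group on the horizontal axes; bars are the mean ± SD of 5 libraries. Prnp was between 695 and 841 FPKM in the 10 TG libraries and between 412 and 528 in the 10 WT libraries.

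The libraries also differed in ways that cross the groups. On the component that held 23.9% of the variance between libraries (PC1), WT10M replicate 5 and TG10M replicates 1 and 5 scored 26.2 to 30.9, and the 17 others -12.1 to 2.52. Among these 17 it also parted the genotypes, with -12.1 to -6.34 in 9 WT libraries and -1.90 to 2.52 in 8 TG libraries. The 3 libraries are called the set apart, and the largest 10-month differences and the medians of lists that passed are also given for it and for the 7 other 10-month libraries. Hsp90aa1 (ENSMUSG00000021270), a cytosolic chaperone, had 13.9 to 20.5 FPKM in the set apart and in TG03M replicates 2 to 5, and 532 to 687 FPKM in the 13 others. Apart from these 3 libraries, mt-Co1, a mitochondrially encoded subunit of cytochrome c oxidase, separated the genotypes, with 5998 to 6915 FPKM in 9 WT libraries and 8514 to 10633 FPKM in 8 TG libraries. In the set apart mt-Co1 had 11182 to 13045 FPKM, the highest value in its WT library. Ttr, a marker of choroid plexus epithelium, ranged from 4.79 to 996 FPKM among the 20 libraries.

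**Figure D2:**
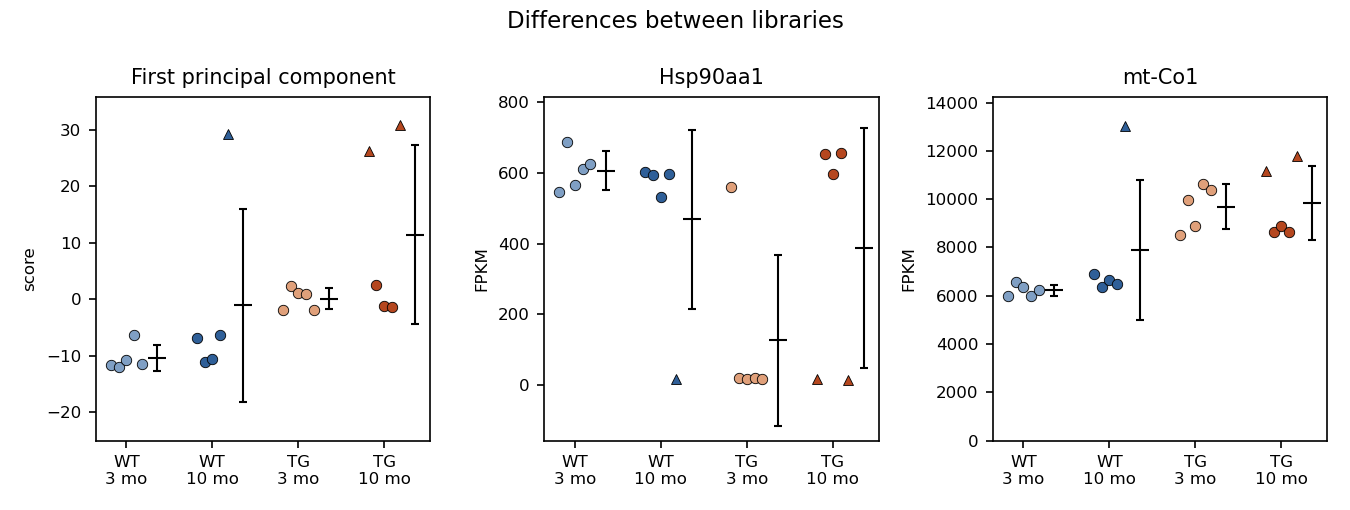
PC1 score, Hsp90aa1 FPKM and mt-Co1 FPKM (vertical axes) of each library, by group on the horizontal axes; triangles mark WT10M replicate 5 and TG10M replicates 1 and 5, and bars are the mean ± SD of 5 libraries. The triangles lie at PC1 scores of 26.2 to 30.9, Hsp90aa1 below 20.5 FPKM and mt-Co1 above 11182 FPKM.

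At 10 months the transgenic cortex held more RNA of astrocyte, microglia, complement and antigen presentation genes. Gfap (ENSMUSG00000020932; chromosome 11, 102887336 to 102900912, minus strand), the intermediate filament of astrocytes, rose by 1.34 (SE 0.16, adjusted p = 0.000134, n = 5 per group, limma), from 46.5 ± 7.54 to 122 ± 37.6 FPKM. C4b (ENSMUSG00000073418; chromosome 17, 34728380 to 34743882, minus strand), a complement component, rose by 1.08 (SE 0.09, adjusted p = 1.17e-06), from 6.11 ± 0.750 to 13.5 ± 1.63 FPKM. Tyrobp (ENSMUSG00000030579), the signalling adaptor of Trem2 in microglia, rose by 1.03 (SE 0.14, adjusted p = 0.000742), from 25.5 ± 6.82 to 51.5 ± 7.50 FPKM. Cst7 (ENSMUSG00000068129; chromosome 2, 150570415 to 150578944, plus strand), a cystatin of activated microglia with a mean FPKM under 1, rose by 2.20 (SE 0.18, adjusted p = 1.12e-06), from 0.156 ± 0.101 to 2.63 ± 0.994 FPKM. These differences had the same sign in the 7 other libraries and in the set apart, at 1.54 and 1.09 for Gfap, 1.06 and 1.20 for C4b, 1.14 and 0.51 for Tyrobp, and 2.43 and 1.64 for Cst7.

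With limma, 80 genes rose and 7 fell at 10 months. Among the largest rises were also the class II invariant chain Cd74 (ENSMUSG00000024610), by 1.04 (SE 0.18, adjusted p = 0.00782), the class II gene H2-Ab1 (ENSMUSG00000073421), by 0.97 (SE 0.16, adjusted p = 0.00410), and the lysozyme gene Lyz2 (ENSMUSG00000069516), by 0.96 (SE 0.14, adjusted p = 0.00198). Ly86 (ENSMUSG00000021423) rose by 0.92 (adjusted p = 0.0171), a call that ended without WT10M replicate 3 or TG10M replicate 1 (highest adjusted p = 0.0698). Cd84 (ENSMUSG00000038147) rose by 0.82 (adjusted p = 0.0233), a call that ended without WT10M replicates 1 or 3 or TG10M replicates 1 or 4 (highest adjusted p = 0.0885). In the 7 other libraries and in the set apart the differences were 1.11 and 0.94 for Cd74, 0.83 and 1.06 for H2-Ab1, 0.99 and 0.83 for Lyz2, 0.90 and 0.56 for Ly86, 0.72 and 0.91 for Cd84, and 0.85 and 0.64 for Prnp. The largest difference was that of Lars2 (ENSMUSG00000035202), the mitochondrial leucyl-tRNA synthetase, at 4.64 (SE 0.84, adjusted p = 0.0118), from 25.4 ± 36.9 to 656 ± 714 FPKM. It was 6.63 in the 7 other libraries and -0.02 in the set apart. Lars2 overlaps sequence that resembles ribosomal RNA, so its values are uncertain. The 7 falls were Pparg (-0.59, adjusted p = 0.0422), Cradd (-0.51, 0.0454), Zcchc10 (-0.50, 0.0392), Clip4 (-0.34, 0.0452), the clock gene Per3 (-0.28, 0.0422), the neuropeptide Y receptor gene Npy1r (-0.26, 0.0305) and Tmcc2 (-0.20, 0.0458). In the 7 other libraries and in the set apart these were -0.46 and -0.072 for Clip4, -0.64 and -0.14 for Zcchc10, -0.60 and -0.30 for Cradd, -0.56 and -0.65 for Pparg, -0.34 and -0.22 for Per3, -0.27 and -0.23 for Npy1r, and -0.18 and -0.16 for Tmcc2. Each of these 7 calls ended without WT10M replicate 3 and without WT10M replicate 4, with a highest adjusted p of 0.111 to 0.166, and leaving out any 10-month library but WT10M replicate 5 ended at least 1 of them.

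The microglia and immune lists, fixed before the data were examined, rose together at 10 months in camera, a set test of limma, with n = 5 per group. Of 15 tested genes of disease-associated microglia, 7 rose and 12 rose when adjusted over the list alone, with a median of 0.55 (adjusted p = 5.08e-15; adjusted p = 7.48e-05 with an estimated correlation). Besides Cst7, Tyrobp and Lyz2 they included the receptor kinase Axl, which rose by 0.39 (SE 0.06, adjusted p = 0.00167). Of 13 genes of antigen presentation, 6 rose and 10 rose when adjusted over the list alone, with a median of 0.64 (adjusted p = 4.60e-14; adjusted p = 0.0133 with an estimated correlation), among them H2-D1 by 0.68 (SE 0.11, adjusted p = 0.00410). Of 13 genes of complement and Fc receptors, 2 rose and 10 rose when adjusted over the list alone, with a median of 0.44 (adjusted p = 5.43e-12; adjusted p = 0.0174 with an estimated correlation). They were C4b and C1qa, which rose by 0.74 (adjusted p = 0.0171) and whose call ended without WT10M replicates 1 or 3 or TG10M replicates 1 or 4. Of 15 genes of the type I interferon response, 0 rose over all genes and 13 when adjusted over the list alone, with a median of 0.52 (adjusted p = 2.49e-11; adjusted p = 0.0499 with an estimated correlation). Ifitm3 was at 0.74 (adjusted p = 0.0656) and Usp18 at 0.66 (adjusted p = 0.0743). Of 12 genes of homeostatic microglia, 1 rose over all genes and 9 rose when adjusted over the list alone, with a median of 0.28 (adjusted p = 1.33e-08; adjusted p = 0.0366 with an estimated correlation). Medians in the 7 other libraries and in the set apart were 0.50 and 0.50 for disease-associated microglia, 0.59 and 0.52 for antigen presentation, 0.48 and 0.20 for complement, 0.42 and 0.71 for interferon response and 0.29 and 0.14 for homeostatic microglia. No gene of these 5 lists fell. Without WT10M replicate 5, 10 antigen presentation, 9 complement and 9 homeostatic microglia genes rose over all genes. The set apart then holds TG libraries only, so these higher counts cannot tell genotype from that set. No homeostatic microglia gene rose over all genes without WT10M replicates 1 to 4 or TG10M replicates 1, 4 or 5.

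Astrocyte, lysosome and oligodendrocyte lists also rose at 10 months in camera. Of 12 reactive astrocyte genes, 3 rose and 7 rose when adjusted over the list alone, with a median of 0.32 (adjusted p = 1.07e-07; adjusted p = 0.0427 with an estimated correlation). They were Gfap, the lipopolysaccharide co-receptor Cd14 by 0.65 (adjusted p = 0.0149) and the serine protease inhibitor Serpina3n by 0.70 (adjusted p = 0.0230). The calls of Cd14 and Serpina3n ended without WT10M replicate 3 or TG10M replicates 1 or 4, and that of Serpina3n also without WT10M replicate 1 or TG10M replicate 3. Of 12 general astrocyte genes, 1 rose, the water channel Aqp4 by 0.52 (SE 0.08, adjusted p = 0.00162), and 5 rose when adjusted over the list alone, with a median of 0.20 (adjusted p = 3.03e-05; adjusted p = 0.0423 with an estimated correlation). Of 16 genes of lysosome and autophagy, 2 rose, the cathepsins Ctsz by 0.56 (SE 0.08, adjusted p = 0.000783) and Ctsd by 0.49 (SE 0.07, adjusted p = 0.00162). In this list 9 rose when adjusted over the list alone, with a median of 0.15 (adjusted p = 1.75e-10; adjusted p = 0.0174 with an estimated correlation). Of 12 oligodendrocyte precursor genes, 0 rose over all genes and 1 when adjusted over the list alone, with a median of 0.15 (adjusted p = 0.00102; adjusted p = 0.0366 with an estimated correlation). Itpr2 was at 0.21 (adjusted p = 0.136). Of 13 oligodendrocyte and myelin genes, 0 rose over all genes and 4 when adjusted over the list alone, with a median of 0.19 (adjusted p = 5.12e-05; adjusted p = 0.170 with an estimated correlation). The myelin basic protein gene Mbp was at 0.23 (adjusted p = 0.155). Medians in the 7 other libraries and in the set apart were 0.31 and 0.36 for reactive astrocyte, 0.22 and 0.13 for astrocyte, 0.18 and 0.09 for lysosome, 0.16 and 0.17 for precursor and 0.16 and 0.21 for myelin genes. Over all genes, 6 reactive astrocyte, 5 astrocyte and 8 lysosome genes rose without WT10M replicate 5, when the set apart holds TG libraries only. Without TG10M replicate 2, 2 astrocyte genes rose.

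Mural, endothelial, collagen, mitochondrially encoded, postsynaptic and striatum lists passed camera at 10 months with the preset correlation only. Of 11 mural cell genes, 1 rose, the vitronectin gene Vtn by 0.58 (adjusted p = 0.0237), and 4 rose when adjusted over the list alone, with a median of 0.22 (adjusted p = 1.80e-05; adjusted p = 0.0509 with an estimated correlation). The Vtn call ended without WT10M replicates 1, 3 or 4 or TG10M replicate 1. Of 12 endothelial genes, 0 rose over all genes and 3 when adjusted over the list alone, with a median of 0.25 (adjusted p = 5.13e-05; adjusted p = 0.0921 with an estimated correlation). Pecam1 was at 0.36 (adjusted p = 0.111). Without WT10M replicate 5 the endothelial median was 0.15, with 1 rise over all genes, and 2 mural genes rose. Of 13 genes of collagen and matrix, 0 rose over all genes and 1 when adjusted over the list alone, with a median of 0.17 (adjusted p = 0.00911; adjusted p = 0.285 with an estimated correlation). The list's call ended without WT10M replicate 5 (median 0.096, adjusted p = 0.193). Of 13 mitochondrially encoded genes, 0 rose over all genes and 1 when adjusted over the list alone, with a median of 0.27 (adjusted p = 0.00165; adjusted p = 0.340 with an estimated correlation). This median was 0.48 in the 7 other libraries and -0.23 in the set apart, and the call ended without TG10M replicate 3 (adjusted p = 0.0845). Of 14 postsynaptic genes, 0 fell, also when adjusted over the list alone, with a median of -0.06 (adjusted p = 0.0141; adjusted p = 0.340 with an estimated correlation). The call ended without TG10M replicate 5 (adjusted p = 0.0693), and the median was -0.034 without TG10M replicate 2 and -0.097 without TG10M replicate 3. Dlg4, the scaffold PSD-95, was at -0.22 (adjusted p = 0.210) and the glutamate receptor gene Gria1 at -0.20 (adjusted p = 0.212). Of 11 striatum genes, 0 fell, also when adjusted over the list alone, and all 11 values were negative. Their median was -0.50 (adjusted p = 5.12e-05; adjusted p = 0.340 with an estimated correlation), -0.71 in the 7 other libraries and -0.11 in the set apart. Without TG10M replicate 2 the striatum median was -0.29 (adjusted p = 0.0107). Medians in the 7 other libraries and in the set apart were 0.27 and 0.28 for mural, 0.23 and 0.46 for endothelial, 0.12 and 0.34 for collagen and -0.062 and -0.0033 for postsynaptic genes. Drd1, the dopamine receptor of striatal neurons, ranged from 7.68 to 21.0 FPKM in TG10M and from 19.4 to 23.5 FPKM in WT10M.

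**Figure D3:**
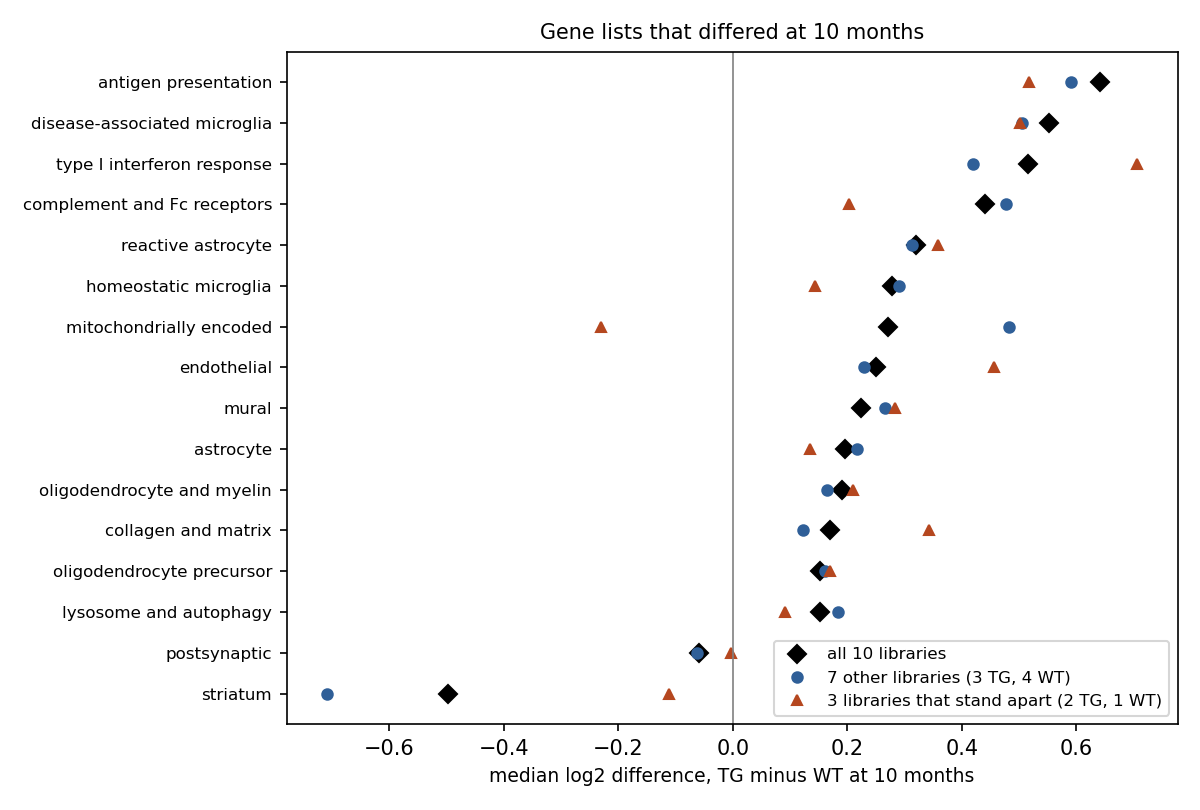
Median log2 difference between TG and WT at 10 months (horizontal axis) of each list that passed camera (vertical axis), over all 10 libraries (black diamonds), the 7 other libraries (3 TG, 4 WT; blue circles) and the set apart (2 TG, 1 WT; red triangles). The mitochondrially encoded list is at 0.48 in the 7 other libraries and at -0.23 in the set apart.

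The other 18 lists did not pass at 10 months. Their medians and camera adjusted p were -0.08 and 0.0745 for excitatory neurons, 0.06 and 0.631 for inhibitory neurons, -0.08 and 0.257 for presynaptic, 0.06 and 0.981 for immediate early and 0.15 and 0.571 for neuropeptide genes. They were 0.06 and 0.299 for the unfolded protein response, 0.08 and 0.702 for cytosolic chaperones, 0.07 and 0.154 for nuclear genes of oxidative phosphorylation, 0.00 and 0.978 for the cytosolic ribosome and -0.07 and 0.299 for tau kinases, phosphatases and microtubule proteins. They were 0.04 and 0.978 for cholesterol biosynthesis, -0.01 and 0.925 for developmental and proliferating, -0.22 and 0.383 for choroid plexus, 0.01 and 0.978 for hippocampus and 0.13 and 0.245 for thalamus genes. They were 0.15 and 0.925 for blood, -0.09 and 0.159 for circadian clock and 0.10 and 0.0784 for glucocorticoid response genes. The means of the inhibitory neuron, neuropeptide and hippocampus lists, each at -0.01, differed in sign from their medians, and the tests of the immediate early and cytosolic ribosome lists pointed down.

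The count of 87 genes at 10 months depended on single libraries. It was 35, 49, 28 and 38 without WT10M replicates 1 to 4, 28, 51, 36 and 47 without TG10M replicates 1, 3, 4 and 5, and 1600 without WT10M replicate 5. WT10M replicate 5 is the only WT library of the set apart, so without it the set apart holds TG libraries only. The 1600 genes, and the 10-month list results without this library, cannot tell genotype from the set apart. Without the set apart 326 genes passed, among them 73 of the 87.

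At 3 months 6 of 13 mitochondrially encoded RNAs rose in transgenic cortex, and the list passed camera (adjusted p = 3.10e-14; adjusted p = 0.0512 with an estimated correlation). The cytochrome b gene mt-Cytb (ENSMUSG00000064370) rose by 1.31 (SE 0.17, adjusted p = 0.00112, n = 5 per group, limma), from 433 ± 34.8 to 1108 ± 310 FPKM. The complex I gene mt-Nd1 (ENSMUSG00000064341) rose by 1.19 (SE 0.19, adjusted p = 0.00644), from 932 ± 42.5 to 2183 ± 571 FPKM, and mt-Nd4 (ENSMUSG00000064363) by 1.25 (SE 0.19, adjusted p = 0.00518). For mt-Cytb the difference was 1.48 for the 4 TG03M libraries low in Hsp90aa1 and 0.64 for TG03M replicate 1, which was not. Sh3bgrl3 (ENSMUSG00000028843) rose by 0.59 (SE 0.07, adjusted p = 0.000132), from 57.0 ± 2.62 to 86.6 ± 8.63 FPKM. Suclg1 (ENSMUSG00000052738), a subunit of the citric acid cycle enzyme succinyl-CoA ligase, fell by 0.32 (SE 0.05, adjusted p = 0.00518), from 61.0 ± 0.920 to 48.7 ± 1.24 FPKM.

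With limma, 38 genes rose and 3 fell at 3 months. The largest rises also included mt-Atp8 by 1.28 (adjusted p = 0.0324), Endou by 1.17 (adjusted p = 0.0250), mt-Nd2 by 1.01 (adjusted p = 0.0163) and mt-Nd5 by 0.89 (adjusted p = 0.0307). Sox10, a transcription factor of the oligodendrocyte lineage, rose by 0.70 (adjusted p = 0.0324). Arl2bp fell by 0.26 (adjusted p = 0.0367) and Paip2b by 0.25 (adjusted p = 0.0198). Each of these 7 calls ended without WT03M replicate 4, without TG03M replicate 2 and without TG03M replicate 5, with a highest adjusted p of 0.0637 to 0.119, and leaving out any 3-month library but TG03M replicate 1 ended at least 1 of them. The count of 41 was 15, 12, 11 and 13 without WT03M replicates 1, 3, 4 and 5, 108 without TG03M replicate 1, and 12, 21, 12 and 11 without TG03M replicates 2 to 5. With the 7 libraries low in Hsp90aa1 as a covariate 4 genes passed, and Prnp, Rac1 and Sh3bgrl3 were kept of the 41, of which 41 had the same sign. No WT03M library is low in Hsp90aa1, so this fit rests on TG03M replicate 1 and on the difference between the sets at 10 months, and it put mt-Cytb at 1.07, Suclg1 at -0.28 and Arl2bp at -0.16. The set apart holds no 3-month library, but it enters the spread of the fit, and 473 genes passed without it. All 38 genes that rose at 3 months had positive differences at 10 months, where 8 of them rose (0.222 if independent): Atp5d, Clu, Eef1a2, Gm2a, Prnp, Rac1, Sh3bgrl3 and Slc38a3. The comparisons are not independent, as they share each gene's spread in one fit, and PC1 parts the genotypes at both ages outside the set apart. For the 40 called genes other than Prnp, the median difference in the 3-month direction was 0.29 in the 7 other 10-month libraries and 0.012 in the set apart.

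Lists that passed camera at 3 months were all higher in transgenic cortex, and 0 of the 5 passed with an estimated correlation. Of 13 mitochondrially encoded genes, 6 rose and 9 rose when adjusted over the list alone, with a median of 0.89 (adjusted p = 3.10e-14; adjusted p = 0.0512 with an estimated correlation). The median was 1.04 for the 4 TG03M libraries low in Hsp90aa1 and 0.32 for TG03M replicate 1, and 3 genes rose without WT03M replicates 4 or 5 or TG03M replicates 2, 4 or 5. Of 12 oligodendrocyte precursor genes, Sox10 rose and 2 rose when adjusted over the list alone, with a median of 0.13 (adjusted p = 0.000305; adjusted p = 0.0512 with an estimated correlation). Over all genes 2 rose without TG03M replicate 1, and 0 without any other 3-month library but WT03M replicate 2. Of 10 choroid plexus genes, 0 rose over all genes and 1 when adjusted over the list alone, with a median of 0.96 (adjusted p = 9.27e-05; adjusted p = 0.657 with an estimated correlation). The choroid plexus median was 0.61 without TG03M replicate 1 and 0.60 without TG03M replicate 4. The prolactin receptor gene Prlr was at 1.31 (adjusted p = 0.227), and Ttr was at 810 FPKM in TG03M replicate 1 and 996 FPKM in TG03M replicate 4, against 4.79 to 31.3 FPKM in WT03M. Of 13 oligodendrocyte and myelin genes, 0 rose over all genes and 1 when adjusted over the list alone, with a median of 0.12 (adjusted p = 0.00481; adjusted p = 0.657 with an estimated correlation). The call ended without TG03M replicate 2 (adjusted p = 0.0517). Of 12 immediate early genes, 0 rose, also when adjusted over the list alone, with a median of 0.43 (adjusted p = 0.0384; adjusted p = 0.657 with an estimated correlation). It was -0.53 for TG03M replicate 1 and 0.62 for the others, and the call ended without WT03M replicate 4 (median 0.14), WT03M replicate 5 or TG03M replicates 2 or 3. The number of lists was 8, 12, 8 and 10 without WT03M replicate 1, WT03M replicate 2, TG03M replicate 1 and TG03M replicate 3. The disease-associated microglia list had a median of 0.00 (adjusted p = 0.323) and the reactive astrocyte list of 0.14 (adjusted p = 0.145). Median and test differed in sign for the presynaptic and circadian clock lists, each with a median of -0.00, and for the developmental list, with a median of -0.03 (adjusted p = 0.868). Mean and test differed in sign for the cytosolic chaperone list, with a mean of -0.17, a median of 0.06 and a test pointing up (adjusted p = 0.393). This list holds Hsp90aa1, at 16.2 to 20.5 FPKM in TG03M replicates 2 to 5 and 547 to 687 FPKM in WT03M.

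The genotype difference was larger at 10 than at 3 months for 5 genes, tested as the interaction of genotype and age. Among them were Cst7 by 2.27 (SE 0.26, adjusted p = 0.000419, n = 5 per group, limma), Gfap by 1.40 (SE 0.22, adjusted p = 0.0122), and C4b by 1.03 (SE 0.13, adjusted p = 0.00113). The others were Cyba by 0.88 (SE 0.14, adjusted p = 0.0122) and Ctsz by 0.61 (SE 0.11, adjusted p = 0.0465). Cyba (ENSMUSG00000006519; chromosome 8, 122424776 to 122432930, minus strand), a subunit of the phagocyte NADPH oxidase, had 8.82 ± 1.19 FPKM in WT03M, 7.95 ± 0.484 in TG03M, 8.40 ± 0.521 in WT10M and 14.5 ± 2.31 in TG10M. Ctsz (ENSMUSG00000016256; chromosome 2, 174427493 to 174439039, minus strand) had 27.4 ± 1.76, 26.5 ± 1.61, 31.1 ± 3.35 and 46.0 ± 4.91 FPKM in the same order. The Ctsz call was kept only without WT03M replicate 3, WT10M replicate 4 or TG10M replicate 5, and ended without the set apart, where Cst7, Gfap, C4b and Cyba passed.

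In the interaction, 12 lists passed camera upward and 8 downward, 2 of them with an estimated correlation as well. Disease-associated microglia had a median of 0.43 (adjusted p = 2.16e-13; adjusted p = 0.000151 with an estimated correlation), with Cst7 passing over all genes and 8 genes when adjusted over the list alone. Antigen presentation had a median of 0.57 (adjusted p = 6.81e-12; adjusted p = 0.0272 with an estimated correlation), with 0 and 7 genes. The other upward lists had camera adjusted p of 1.08e-07 for complement, 1.08e-07 for lysosome, 2.25e-06 for interferon response, 0.000127 for homeostatic microglia and reactive astrocyte, 0.00233 for astrocyte and nuclear oxidative phosphorylation, 0.00641 for endothelial and mural and 0.0433 for collagen genes. With an estimated correlation these had, in the same order, adjusted p = 0.0838, 0.0699, 0.181, 0.157, 0.157, 0.157, 0.377, 0.263, 0.250 and 0.405. Adjusted over the list alone, 2 complement, 2 lysosome, 3 reactive astrocyte and 1 astrocyte gene passed, where C4b, Ctsz and Gfap passed over all genes. Downward, the camera adjusted p was 3.19e-06 for the mitochondrially encoded list (median -0.59), 3.53e-06 for choroid plexus (-1.17), 0.00228 for postsynaptic (-0.17), 0.00478 for excitatory neuron (-0.17), 0.0174 for striatum (-0.34), 0.0187 for circadian clock (-0.09), 0.0280 for immediate early (-0.32) and 0.0284 for presynaptic genes (-0.04). With an estimated correlation these had, in the same order, adjusted p = 0.157, 0.250, 0.242, 0.313, 0.633, 0.110, 0.652 and 0.405, and 3 mitochondrially encoded genes passed when adjusted over the list alone. The endothelial and circadian calls ended without WT10M replicate 5, and the striatum call without WT03M replicate 5, TG03M replicate 2 or TG10M replicate 2. The presynaptic call ended without WT03M replicates 2 or 3, WT10M replicates 1, 3 or 4, TG03M replicate 5 or TG10M replicates 1 or 5. The immediate early call ended without WT03M replicate 4, WT10M replicates 2, 3 or 5, TG03M replicates 2 or 3 or TG10M replicate 2. The collagen call ended without WT03M replicates 1 or 2, WT10M replicates 1, 3 or 5, TG03M replicates 2 or 3 or TG10M replicates 2, 3 or 5. Medians that moved by over 1.5 times with 1 library left out were those of choroid plexus (-0.77) and astrocyte genes (0.15) without TG03M replicate 4, of circadian clock genes (-0.061) without TG10M replicate 3 and of collagen genes (0.060) without WT10M replicate 5. The excitatory neuron median was -0.11 without TG10M replicate 1 and the postsynaptic median -0.11 without TG10M replicate 5. The presynaptic median was -0.11, -0.092 and -0.081 without WT10M replicate 5, TG03M replicate 3 and TG10M replicate 2. The striatum median was -0.10, -0.16 and -0.13 without WT03M replicate 5, TG03M replicate 2 and TG10M replicate 2. The immediate early median was -0.48, -0.042, -0.58, -0.18, -0.54 and -0.16 without WT03M replicates 1 and 4, WT10M replicates 1 and 2 and TG03M replicates 1 and 3. Over all genes 2 disease-associated microglia genes passed without WT03M replicate 3 or WT10M replicates 4 or 5.

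Between 3 and 10 months in wild-type cortex, C4b rose by 0.68 (SE 0.09, adjusted p = 0.00592, n = 5 per group, limma), from 3.63 ± 0.479 to 6.11 ± 0.750 FPKM. With limma, 7 genes rose and 2 fell. The others that rose were Endou (ENSMUSG00000022468) by 1.24 (adjusted p = 0.0270), Abca8a by 0.84 (adjusted p = 0.0195), Slc38a6 by 0.60 (adjusted p = 0.0241) and Tmem106c by 0.49 (adjusted p = 0.0149). Endou was at 0.214 ± 0.0748 FPKM in WT03M, 1.21 ± 0.359 in WT10M, 1.15 ± 0.414 in TG03M and 1.60 ± 0.767 in TG10M. Its call here and its call between genotypes at 3 months share the low WT03M values and are not separate results. 1700048O20Rik rose by 0.96 and Gm765 by 0.94, both named after their values were seen. The receptor kinase gene Met fell by 0.53 (adjusted p = 0.0241) and Sox4, a transcription factor of immature neurons, by 0.33 (adjusted p = 0.0285). The calls of Endou, Abca8a, Slc38a6, Tmem106c, Met and Sox4 ended without WT03M replicates 1, 2 or 4 or WT10M replicate 1, and that of Sox4 whichever library was left out, with a highest adjusted p of 0.0608 to 0.133. Without WT10M replicate 5 those of Endou, Abca8a, Slc38a6, Met and Gm765 ended too. The call of Endou also ended without WT03M replicate 5 or WT10M replicates 3 or 4, that of Abca8a without WT10M replicate 4, that of Slc38a6 without WT10M replicates 2 or 3, and that of Met without WT03M replicate 5 or WT10M replicates 2, 3 or 4. The count of 9 was 1, 1 and 1 without WT03M replicates 1, 2 and 4, and 1, 5, 4 and 4 without WT10M replicates 1, 3, 4 and 5.

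Among lists, 5 rose and 4 fell with age in wild-type cortex in camera, 0 of them with an estimated correlation. Complement had a median of 0.19 (adjusted p = 0.000399; adjusted p = 0.558 with an estimated correlation) and antigen presentation of 0.20 (adjusted p = 0.00382; adjusted p = 0.669 with an estimated correlation). In complement C4b passed over all genes and 1 gene when adjusted over the list alone, and in antigen presentation 0 and 0. Collagen and matrix genes had a median of -0.23 (adjusted p = 0.000233; adjusted p = 0.336 with an estimated correlation), with 0 falls over all genes and 4 when adjusted over the list alone. The type I collagen gene Col1a2 was at -0.52 (adjusted p = 0.229). Developmental and proliferating genes had a median of -0.14 (adjusted p = 0.00117; adjusted p = 0.284 with an estimated correlation), with Sox4 falling and 2 falls when adjusted over the list alone. The other lists, with 0 genes passing over all genes or over the list alone, were striatum with a median of 0.41 (adjusted p = 0.000339), choroid plexus with 0.73 (adjusted p = 0.00117) and mitochondrially encoded with 0.26 (adjusted p = 0.0106), and downward endothelial with -0.17 (adjusted p = 0.0106) and cytosolic chaperone genes with -0.16 (adjusted p = 0.0296). Each of these 5 had adjusted p = 0.669 with an estimated correlation. The striatum call ended without WT03M replicate 5, the mitochondrial call without WT10M replicate 5, the endothelial call without WT03M replicate 4 or WT10M replicates 3 or 5, and the chaperone call without WT03M replicate 2 or WT10M replicates 3 or 5. The striatum median was 0.18 without WT03M replicate 5, the mitochondrial median 0.11 without WT10M replicate 5, and the endothelial median -0.094 without WT03M replicate 2 and -0.085 without WT10M replicate 5. The chaperone median was 0.0071 without WT03M replicate 2 and -0.25 without WT10M replicate 2, and the antigen presentation median 0.11 without WT03M replicate 5 and 0.081 without WT10M replicate 5. The chaperone list holds Hsp90aa1, at 16.6 FPKM in WT10M replicate 5. Ttr was at 492 FPKM in WT10M replicate 1 and 339 FPKM in WT10M replicate 3, above the 4.79 to 31.3 FPKM of WT03M.

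Between 3 and 10 months in transgenic cortex, the lists of antigen presentation, disease-associated microglia and complement genes rose in camera, with adjusted p = 0.00565, 0.000132 and 0.0233 with an estimated correlation. C4b rose by 1.71 (SE 0.09, adjusted p = 9.23e-10, n = 5 per group, limma), from 3.76 ± 0.233 to 13.5 ± 1.63 FPKM, and Gfap by 1.46 (SE 0.16, adjusted p = 2.98e-05), from 43.0 ± 6.30 to 122 ± 37.6 FPKM. Trem2 (ENSMUSG00000023992), a lipid receptor of microglia, rose by 1.08 (SE 0.13, adjusted p = 0.000107), from 6.61 ± 0.927 to 14.6 ± 2.20 FPKM, and Cst7 by 2.42 (SE 0.18, adjusted p = 2.04e-07). Spag6l (ENSMUSG00000037708), a gene of motile cilia, rose by 1.27 (SE 0.13, adjusted p = 2.28e-05). With limma, 88 genes rose and 28 fell. Other large rises were Cd84 by 1.23, Lyz2 by 1.23, Bcl2a1b by 1.07, the complement gene C1qb by 1.06 and Tyrobp by 1.03, and H2-Ab1 rose from 1.30 ± 0.225 to 3.18 ± 1.08 FPKM. The Bcl2a1b call ended without TG03M replicates 2, 3 or 4 or TG10M replicate 4, and the C1qb call without TG03M replicate 2 or TG10M replicates 4 or 5. The muscarinic receptor gene Chrm1 (ENSMUSG00000032773) fell by 0.37 (SE 0.06, adjusted p = 0.00688), from 32.6 ± 1.59 to 25.2 ± 2.18 FPKM. Prrg3 (-0.64), Gpr17 (-0.62), Cited2 (-0.49), Fbxo27 (-0.45), Pcdhgc5 (-0.43), Met (-0.42), Tmsb10 (-0.42), Prrt2 (-0.39) and Fbxl16 (-0.38) also fell, with adjusted p of 0.0294 to 0.0425. These 9 calls ended without TG03M replicates 4 or 5 or TG10M replicates 1 or 5, and each other library ended at least 1 of them, with a highest adjusted p of 0.0896 to 0.137. The count of 116 was 76, 75 and 67 without TG03M replicates 2, 3 and 5, and 56 and 62 without TG10M replicates 1 and 5. Without the set apart 73 genes passed, 48 of them among the 116, and with the 7 libraries low in Hsp90aa1 as a covariate 2319 passed. That covariate gives the same term to the set apart (PC1 of 26.2 to 30.9) and to TG03M replicates 2 to 5 (-1.87 to 2.34). As these sets differ, the 2319 need not be an effect of age.

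Of the lists, 9 rose and 9 fell with age in transgenic cortex in camera, 6 of them with an estimated correlation as well. Antigen presentation had a median of 0.66 (adjusted p = 1.25e-16; adjusted p = 0.00565 with an estimated correlation), with 8 rises over all genes and 11 when adjusted over the list alone, among them the cathepsin Ctss by 0.91 (adjusted p = 0.000539). Disease-associated microglia had a median of 0.50 (adjusted p = 5.33e-14; adjusted p = 0.000132 with an estimated correlation), with 5 and 9 rises. Complement had a median of 0.49 (adjusted p = 1.07e-11; adjusted p = 0.0233 with an estimated correlation), with 6 and 8, among them C1qa by 0.98 (adjusted p = 0.000833), and 3 rose over all genes without TG10M replicate 4. Lysosome and autophagy had a median of 0.12 (adjusted p = 1.03e-07; adjusted p = 0.0364 with an estimated correlation), with 2 and 7 rises, among them Ctsz by 0.78 (adjusted p = 1.12e-05). Homeostatic microglia, with 3 and 7 rises, had a median of 0.21 (adjusted p = 6.10e-07; adjusted p = 0.0589 with an estimated correlation). Among the 3 were the microglial receptor genes Cx3cr1 by 0.26 (adjusted p = 0.0319) and Gpr34 by 0.50 (adjusted p = 0.0366), whose calls both ended without TG03M replicates 3 or 5 or TG10M replicates 1, 4 or 5, with a highest adjusted p of 0.0962 and 0.120. That of Cx3cr1 also ended without TG03M replicate 2, and that of Gpr34 without TG03M replicate 4. The count of 3 was 1 without TG03M replicate 3 or TG10M replicates 1, 4 or 5. Reactive astrocyte genes, with 4 and 4 rises and Serpina3n by 0.77 (adjusted p = 0.00778), had a median of 0.09 (adjusted p = 0.000613; adjusted p = 0.193 with an estimated correlation). Their median was 0.23 without TG03M replicate 4, and 2 rose over all genes without TG10M replicate 1. Interferon response (median 0.43, adjusted p = 3.00e-07), astrocyte (0.10, 0.00524) and cytosolic ribosome genes (0.12, 0.00711) rose as lists, with adjusted p = 0.167, 0.173 and 0.664 with an estimated correlation. They had 0 rises over all genes and 5, 4 and 0 when adjusted over the list alone. The astrocyte median was 0.059 without TG03M replicate 1 and 0.064 without TG10M replicate 3, with 1 rise over all genes, and the ribosome median 0.078 and 0.071 without TG10M replicates 1 and 5. Circadian clock genes had a median of -0.13 (adjusted p = 0.00648; adjusted p = 0.0364 with an estimated correlation), with 0 falls over all genes and 2 when adjusted over the list alone. Tau kinases, phosphatases and microtubule proteins had a median of -0.10 (adjusted p = 0.00707; adjusted p = 0.0364 with an estimated correlation), with 0 and 1.

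The excitatory neuron and synaptic lists were lower at 10 than at 3 months in transgenic cortex with the preset correlation, and the inhibitory neuron list did not pass (median -0.05, adjusted p = 0.612). Excitatory neuron genes had a median of -0.20 (adjusted p = 0.000436; adjusted p = 0.193 with an estimated correlation) and postsynaptic genes of -0.18 (adjusted p = 0.00114; adjusted p = 0.193 with an estimated correlation). Presynaptic genes had a median of -0.13 (adjusted p = 0.00648; adjusted p = 0.326 with an estimated correlation). No gene of these 3 lists fell over all genes, and 0, 2 and 0 fell when adjusted over the list alone, with Dlg4 at -0.29 (adjusted p = 0.0756). Without the set apart their medians were -0.10, -0.10 and -0.07, and without TG03M replicate 5 -0.13, -0.10 and -0.080. The postsynaptic median was also -0.12 without TG03M replicate 4. Developmental and proliferating genes had a median of -0.22 (adjusted p = 0.00524; adjusted p = 0.0979 with an estimated correlation), with Sox4 falling by 0.26 (adjusted p = 0.0377) and Tmsb10, and 4 falls when adjusted over the list alone. The Sox4 call was kept only without TG03M replicate 5 or TG10M replicate 3. Over all genes 1 fell without TG03M replicates 1 or 5 or TG10M replicates 2 or 4, and 0 without TG03M replicates 2, 3 or 4 or TG10M replicates 1 or 5. Mitochondrially encoded (-0.32, adjusted p = 0.0103), immediate early (-0.32, adjusted p = 0.0422) and cytosolic chaperone genes (-0.16, adjusted p = 0.0422) also passed as lists, with adjusted p = 0.542, 0.678 and 0.678 with an estimated correlation. They had 0 falls over all genes and 2, 0 and 0 when adjusted over the list alone. The mitochondrial call ended without TG03M replicate 4 or TG10M replicate 2, and the immediate early call without TG03M replicates 2, 3, 4 or 5 or TG10M replicate 2. The chaperone call ended without TG03M replicates 3, 4 or 5 or TG10M replicates 1 or 5, and the ribosome call without TG03M replicate 5. The mitochondrial median was -0.20 without TG03M replicate 4, and the immediate early median -0.56 without TG03M replicate 1 and -0.19 without TG10M replicate 2. The chaperone median was -0.28, -0.25 and -0.082 without TG03M replicates 1, 2 and 4 and -0.24 without TG10M replicates 3 or 4. The chaperone list holds Hsp90aa1, which was low in TG03M replicates 2 to 5 and in TG10M replicates 1 and 5.

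Long non-coding RNAs and transcripts of uncertain coding potential (TUCP) were tested on log2(FPKM + 0.1), 3413 transcripts in all, with limma. The annotated RP23-148J20.4 (ENSMUSG00000106540; 4930590L14Rik in GENCODE M21; chromosome 3, 140951876 to 140953247, plus strand, 2 exons) differed between the genotypes at both ages. It was listed at 0 FPKM in 10 of 10 WT libraries and at 0.425 to 1.75 FPKM in the 10 TG libraries (adjusted p = 8.40e-07 at 3 months and 8.18e-08 at 10 months). TUCP_000418 and LNC_000342, a lncRNA assembled by the submitters, share the locus name XLOC_024660 and were also listed at 0 in 10 of 10 WT libraries. They had 0.219 to 0.613 and 0.102 to 1.08 FPKM in the TG libraries (adjusted p = 8.62e-05 and 0.0122 at 3 months, 0.000158 and 0.000442 at 10 months). LNC_000343, of that locus, passed at 3 months (adjusted p = 0.0493), with 1.1e-05 to 0.899 FPKM in the TG libraries and 0 in the WT ones. The 1.1e-05, in TG10M replicate 3, lies far below 1 fragment at the estimated depth.

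At 10 months 6 non-coding transcripts rose and 2 fell, at 3 months 4 rose and 0 fell (215 at an unadjusted p under 0.05), and with age in wild-type cortex 1 rose and 3 fell. 2500004C02Rik (chromosome 2, 153342515 to 153343221, minus strand, 2 exons) had 0.0466 ± 0.0705 FPKM in WT10M against 1.86 ± 0.975 in TG10M, 1.60 ± 0.825 in WT03M and 1.51 ± 0.575 in TG03M (adjusted p = 1.01e-05 for genotype at 10 months, 4.69e-05 for age). LNC_000331, a lncRNA assembled by the submitters, was at most 2.97e-05 FPKM in WT10M (adjusted p = 0.0223 for genotype, 0.0357 for age). Its means were 1.56 ± 0.992 in TG10M, 1.51 ± 0.822 in WT03M and 0.577 ± 0.834 in TG03M. The WT10M values of LNC_000331 and the lowest of 2500004C02Rik (1.27e-05 FPKM) lie far below 1 fragment at the estimated depth. Such values are not measured amounts, so the size of the differences of both transcripts is uncertain. Gm11642 (chromosome 11, 103723950 to 103724532) fell by 1.87 at 10 months (SE 0.33, adjusted p = 0.0118), from 2.51 ± 0.484 to 0.704 ± 0.441 FPKM, and the antisense Gm16135 (chromosome 10, 62998779 to 62999689) by 2.13 (SE 0.44, adjusted p = 0.0468). Yam1 (AY036118 in GENCODE M21; chromosome 17, 39847113 to 39848035), which overlaps ribosomal RNA sequence and whose values are uncertain, rose by 3.60 (SE 0.73, adjusted p = 0.0468). With age in wild-type cortex, the antisense RP24-187P11.2 (Gm42756 in GENCODE M21; chromosome 9, 109537100 to 109552780) rose by 1.63 (SE 0.25, adjusted p = 0.00568) and LNC_000227 fell by 0.80 (SE 0.15, adjusted p = 0.0357). Among 16 lncRNAs chosen by name beforehand, Malat1, Neat1 and Meg3 among them, 0 of 63 tested transcripts passed in limma (lowest adjusted p = 0.261). The median difference of all non-coding transcripts was -0.14 at 10 months, and the fit does not remove it. The count of 8 at 10 months was 5 without WT10M replicates 2, 3 or 4 or TG10M replicates 4 or 5. The count of 4 at 3 months was 2 without TG03M replicates 1, 2 or 4, and the count of 4 with age was 2 without WT03M replicates 1, 2, 4 or 5 or WT10M replicates 1, 2 or 5.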

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

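The tests of exchanged labels, tissue of other regions, length and GC trend, depth, read filter, library sets and genotype were chosen after the result was seen. In 9 of 119 groups of 5 values tested, 1 library lay far from the 4 others, where chance gives about 5.95, and 3 of the 9 were in the set apart. High values were Prnp in WT03M replicate 4 (458 FPKM) and WT10M replicate 5 (528), Gfap in WT03M replicate 4 (51.5), Tmem106c in WT03M replicate 5 (9.84), Lars2 in WT10M replicate 5 (91.2), H2-Ab1 in TG10M replicate 1 (5.05) and Met in TG10M replicate 2 (2.87). Low values were Cd84 in WT10M replicate 3 (0.930 FPKM) and Tmsb10 in TG03M replicate 1 (285).

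The genotype difference changed between 3 and 10 months, tested as an interaction with limma, for Cst7 (2.27), Gfap (1.40), C4b (1.03), Cyba (0.88) and Ctsz (0.61). In camera with the preset correlation it changed upward, by the median log2 difference, for lists of antigen presentation (0.57), disease-associated microglia (0.43), interferon response (0.34), complement (0.29), mural (0.22), endothelial (0.21), reactive astrocyte (0.19), homeostatic microglia (0.16), lysosome (0.14), collagen (0.12), nuclear oxidative phosphorylation (0.11) and astrocyte genes (0.10). With an estimated correlation, antigen presentation and disease-associated microglia passed, and the 10 others had adjusted p = 0.0699 to 0.405 with an estimated correlation. With the preset correlation it changed downward for choroid plexus (-1.17), mitochondrially encoded (-0.59), striatum (-0.34), immediate early (-0.32), postsynaptic (-0.17), excitatory neuron (-0.17), circadian clock (-0.093) and presynaptic genes (-0.045), of which 0 passed with an estimated correlation (adjusted p = 0.110 to 0.652 with an estimated correlation). Of 100 splits of the libraries within each age, the real one included, 1 gave as many lists with the preset correlation (20; highest other 18, median of the others 9). No other split drawn reached the count of lists, but 1 came close to it. For genes 6 of 100 splits gave as many (5; highest other 1083), so that chance is not excluded for the count, and the split with 1083 put the whole set apart on one side.

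The set apart (WT10M replicate 5 and TG10M replicates 1 and 5) crosses the genotypes. Exchanged labels are argued against by Prnp, at 528 FPKM in WT10M replicate 5, below the lowest TG library (695). Tissue of striatum, thalamus or choroid plexus, as a source shared by the set apart, is argued against by their 3 lists. In 0 of them did any library of the set apart lie above the highest of the other 7. For choroid plexus this says little of TG10M replicate 1 (list median 1.25, Ttr at 400 FPKM), as WT10M replicate 1 was at 1.98 with Ttr at 492 FPKM. WT10M replicate 5 and TG10M replicate 5 were at 0.56 and 0.014. A trend with transcript length and GC content is argued against by the 8.04% at most of the variance between genes that it accounts for. Tissue of hippocampus stays open, as medians of its list were 1.63 to 2.20 in the set apart and 1.24 to 1.78 in the other 7, with 1 of 3 libraries above their highest, while its marker Prox1 was lower, at 1.37 to 1.64 FPKM against 1.75 to 2.33. The set apart was also sequenced more deeply, at an estimated 28.8 to 30.0 M fragments against 22.5 to 27.0 in the other 7. TG03M replicate 1, outside the set apart, had 30.1 M fragments and a PC1 score of -1.90. Depth was not tested as a source of the set apart. An unrecorded difference in handling or sequencing, tissue of a region without a list or a difference between the animals may also be the source, untested.

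In 7 libraries, the set apart and TG03M replicates 2 to 5, Hsp90aa1 and 14 other genes were lower than in each of the 13 others by over 0.3 on the log2 scale. Their mean differences were -0.83 to -6.13, with a median of -3.47. By the same criterion of 0.3, 0 genes were higher in the 7. Lower ribosome biogenesis as a whole is argued against by the other 32 ribosome biogenesis genes, with a median of -0.057, and sequencing depth by 5 of the 13 libraries that lie within the depth range of the 7. All 8 tested genes with Rrp symbols (ribosomal RNA processing) are among the 15, which prompted the hypothesis of a read filter against sequences named for ribosomal RNA and does not test it. The other 7 of the 15 (Rpl12, Hsp90aa1, Exosc5, Cmtr1, Rrnad1, Dis3 and Emg1) carry no such symbol. Only symbols were searched, not full or former gene names, so these 7 do not count against the filter. The filter stays open, and no biological explanation was tested beyond ribosome biogenesis.

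For the 40 genes other than Prnp called between genotypes at 3 months, the median difference in the 3-month direction was 0.40 at 3 months, 0.29 in the 7 other 10-month libraries, where 40 of 40 kept the sign, and 0.012 in the set apart, where 23 of 40 did. The set apart and the libraries low in Hsp90aa1 are argued against as the whole source by the 40 of 40, since these 7 libraries of both genotypes belong to neither. An unrecorded set that coincides with genotype outside the set apart, where PC1 also parts the genotypes, could give these values. It and genotype cannot be told apart for these genes, as the median and the upper quartile of 0.074 in the set apart rest on 3 libraries, 1 of them WT. Prnp, at 0.64 in the set apart, is not among them.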

How the results depend on the processing

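The alternatives that leave out or adjust for the set apart or the libraries low in Hsp90aa1, and the library set of 3 levels, were chosen after seeing the data. Over all alternatives, results for named genes kept direction and side of the threshold in 1988 cases, lost the call in 501, gained it in 1 and turned in 2, and results for lists kept it in 1430, lost it in 197 and turned in 1. Counts stayed within 1.5 times in 224 cases and moved further in 95. The cause of these moves was not tested, except for the library set of 3 levels. Counts are given for 10 months, 3 months, interaction, age in WT and age in TG.

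With each library left out in turn, gene counts ranged from 28 to 1600, 11 to 108, 4 to 6, 1 to 9 and 56 to 154. The 1600 is without WT10M replicate 5, when the set apart holds TG libraries only. List counts ranged from 15 to 19, 4 to 12, 17 to 21, 7 to 12 and 15 to 19. Non-coding counts ranged from 5 to 10 at 10 months, 2 to 4 at 3 months and 2 to 6 with age in WT. Array weights gave 945 genes at 10 months, 261 at 3 months, 10 in the interaction and 44 with age in WT. A fit of only the groups compared gave 16, 221, 1 (age in WT) and 52 (age in TG), and 5 non-coding transcripts at 10 months. Transcripts instead of genes gave 43, 22, 3, 1 and 46. No filter on low values gave 22 genes at 3 months, a mean FPKM of at least 1 gave 3 in the interaction, and a mean FPKM of at least 0.5 gave 1 non-coding transcript at 3 months. Pseudocount 1 gave 2 non-coding transcripts with age in WT. The share of the called non-coding transcripts at 10 months that were higher in TG was 75%, 88.9% when median-centred and 87.5% after quantile normalization, which gave 8 lists at 3 months.

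With an estimated correlation 9, 0, 2, 0 and 6 lists passed, and with fry 2 at 3 months, 4 in the interaction and 0 with age in WT. Without the set apart 326 genes passed at 10 months, 473 at 3 months and 73 with age in TG, and 10 non-coding transcripts at 3 months and 1 with age in WT. With the set apart as a covariate 178 passed at 10 months, 492 at 3 months and 14 with age in WT, and 9 non-coding transcripts at 3 months and 2 with age in WT. With the libraries low in Hsp90aa1 as a covariate 4 genes passed at 3 months and 2319 with age in TG, and 2 non-coding transcripts at 3 months. This covariate gives the same term to the set apart and to TG03M replicates 2 to 5, which differ on PC1, so the 2319 need not be an effect of age. The library set of 3 levels (other WT, other TG and the set apart) is genotype itself outside the set apart, so its genotype differences rest on 1 WT and 2 TG libraries, and its loss of calls follows from its construction. It gave 2 genes at 10 months, 0 in limma at 3 months (387 at an unadjusted p under 0.05) and 16 with age in WT, and 10 lists at 3 months. With it the value of Lars2 at 10 months was -0.021, that of Suclg1 at 3 months 0.015 and the median of the mitochondrially encoded list at 10 months -0.23, against 4.64, -0.32 and 0.27.

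The replicate number as a block gave 72, 44, 6, 5 and 94 genes and 5 non-coding transcripts at 10 months. Of 20 pairs of libraries with the same number 5 correlated above 0.1, and 5 of 20 libraries correlated best with their own number, so the numbers do not pair the samples. A covariate for sex was not run, since the Y-linked gene Ddx3y was at 22.8 to 28.7 FPKM in all 20 libraries. In simulated data with the real spread, 26 of 100 non-coding transcripts changed by 0.5 were found. Whether the depth of 22.5 to 30.1 M fragments limits this was not tested.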

Other observations

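The tests of transgene insertion and of reads aligned to a similar sequence were chosen after the result was seen. Neuropeptide genes of the hypothalamus differed between libraries of one group, without passing in limma. Oxt, which encodes oxytocin, was at 7.23 FPKM in WT10M replicate 5, 2.92 in TG10M replicate 5 and 0.123 in TG10M replicate 1, and at most 0.413 in the 17 libraries outside the set apart. Avp, which encodes vasopressin, was at 21.8, 14.2 and 0.641 FPKM in the same libraries and at most 3.12 in these 17. The haemoglobin gene Hbb-bs was between 134 and 350 FPKM in 19 libraries and at 1103.5 in TG10M replicate 5. The lncRNA Neat1, a scaffold of nuclear paraspeckles, was not called, with means of 11.9 ± 1.42 FPKM in WT03M, 6.30 ± 1.61 in TG03M, 13.2 ± 4.39 in WT10M and 8.14 ± 1.59 in TG10M.

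LNC_000226, an antisense lncRNA assembled by the submitters, ranged from 1251 to 96107 FPKM. It was at 1251 to 1571 FPKM in the set apart, 2781 to 5676 in TG03M replicates 2 to 5 and 21156 or more in the 13 libraries high in Hsp90aa1. Gm26917 (chromosome 17, 39845074 to 39846245), beside Yam1, was at 3.81 to 17.3 FPKM in the 7 libraries low in Hsp90aa1 and at 289 to 554 in the 13 others.

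Of the features listed at 0 in 10 of 10 WT libraries and above 0 in 10 of 10 TG libraries there were 5, and 0 showed the reverse. They were RP23-148J20.4 on chromosome 3 and 4 assembled transcripts of locus XLOC_024660 (TUCP_000418, LNC_000342, LNC_000343 and LNC_000344), whose coordinates are not given in the sources used here. LNC_000343 counts as above 0 in TG10M replicate 3 only by 1.1e-05 FPKM, far below 1 fragment. Reads of mouse Prnp or Mapt sequence aligned to RP23-148J20.4 are argued against by its longest match with a mouse Prnp or Mapt transcript, 18 bases of 836. The human tau sequence of the transgene was not analysed here, and neither were the sequences of the 4 assembled transcripts, so reads of the transgene stay open for these. Transgene insertion beside the locus could give RNAs of this kind, and 0 annotated features with this pattern lay over 1 Mb away, which rests on the single annotated RNA. The neighbours Unc5c and Bmpr1b were not called in limma at either age. Unc5c was lower in TG at both, at -0.22 (SE 0.06, adjusted p = 0.109) at 10 months and -0.17 (SE 0.06, adjusted p = 0.285) at 3 months. Bmpr1b was at 0.10 (adjusted p = 0.474) at 10 months and -0.12 (adjusted p = 0.541) at 3 months. A strain difference linked to the transgene was not tested.

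Counts were compared with those of other splits of the libraries, with 100 splits each and the real one included. Chance is called not excluded where 5 or more of the 100 splits gave as many. Where fewer did, the count was seldom reached. That does not exclude chance either, as the cut-off was not adjusted for the number of counts tested. For genes 6 splits gave as many at 10 months (87; highest other 3403) and 7 at 3 months (41; highest other 625), so chance is not excluded for either count. The split with 3403 set WT10M replicates 1 to 4 and TG10M replicate 3 against the others, which were the set apart and TG10M replicates 2 and 4. That with 625 set WT03M replicates 1, 3, 4 and 5 and TG03M replicate 1, all high in Hsp90aa1, against the others. Among these others were TG03M replicates 2 to 5, low in Hsp90aa1, and WT03M replicate 2, which was high (687 FPKM). Whether the structure of the libraries gave these 2 counts was not tested. For age 1 split gave as many genes in WT (9; highest other 1) and 1 in TG (116; highest other 15), so no other split drawn reached these counts. For lists, with the preset correlation, 12 splits gave as many at 10 months (16; highest other 24), 85 at 3 months (5; highest other 16) and 47 with age in WT (9; highest other 14), so chance is not excluded. With age in TG 3 splits gave as many lists (18; highest other 21, median of the others 9), so the count was seldom reached, though another split gave more. For non-coding transcripts 3 splits gave as many at 10 months (8; highest other 16), 2 at 3 months (4; highest other 10) and 1 with age in WT (4; highest other 2). These counts were seldom reached, though at 10 and at 3 months another split gave more.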
